A study of Mus musculus with 6 samples.

How the data were processed

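Liver RNA of 6 male mice was sequenced, 3 carrying floxed Prdx1 alleles without Cre (Prdx1 fl/fl, called control below) and 3 carrying the same alleles with an albumin-Cre transgene (Alb-Cre Prdx1 fl/fl, called knockout below). Per the labels, the mice were 8 weeks old at the start and were kept on MCD for 5 weeks. The labels give only this abbreviation, which in liver work usually stands for a methionine- and choline-deficient diet. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was purified, the second strand was marked with dUTP, adapters carried unique molecular identifiers, and read pairs were sequenced on an Illumina NovaSeq instrument.

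The deposited table lists 55401 genes with an estimated count and an FPKM value for each library. Per the submitters' processing notes, the tools included cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with no roles or order given. The same notes list the build mm9, but the gene positions in the table are those of GRCm38. Of 55141 gene identifiers found in the GENCODE M21 annotation of GRCm38, 51957 (94.2%) had the same chromosome, start and end there, so positions are given in GRCm38. Per the file headers, the columns are named wt and AlbCRE with a number. AlbCRE matched the genotype label of the knockout, and wt was assigned to the control genotype because it is the only other genotype in the series.

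The deposited counts were whole numbers that were not scaled between libraries, and they were treated as estimated counts because low values piled up at multiples of 4. In control 1, 854 genes had a count of 4, against 280 genes with a count of 3 and 167 with a count of 5. A read pair was therefore worth about 4 deposited counts, no counting intervals are given, and the deposited counts overstate the number of independent molecules. A group with a count of 0 in all libraries was set to a floor of 12 deposited counts over the group, which is 3 read pairs at 4 counts each. For named genes the same floor was used for a group whose mean was above 0 but below it. The deposited FPKM values, made by the authors, were 0.0001 wherever the count was 0. The planned test for a table of FPKM alone was limma on log2(FPKM + 0.5). The plan named edgeR for a table that also held raw counts, and edgeR was used here on counts that proved to be estimated, not raw.

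Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18931 genes, and libraries were scaled by TMM factors. Genotype was the only term. The quasi-likelihood test (glmQLFit and glmQLFTest) was two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values are counts scaled to a fixed total with the TMM-scaled library sizes. The levels of Prdx1 were also compared by an exact two-sided permutation test.

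Before the data were examined, 39 gene lists were fixed, and 38 of them had the 5 tested members needed for camera (limma 3.58.1), run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated per list, and fry was run beside it. In addition to counts over all tested genes, members were counted with p-values adjusted over the list alone. Genes were named by a rule fixed at the same time. Prdx1 came first, followed by the 12 largest positive and the 12 largest negative log2 fold changes among genes past the threshold whose groups did not overlap. Gene models named Gm plus digits or ending in Rik were left out of this step. Up to 4 members with the smallest p were named in each list. A symbol with several entries was represented by the entry with the highest mean count, and 134 entries repeated a symbol. Genes outside the rule are marked as chosen after their values were seen. Some members that this step would name are not reported here.

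Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE factors, no count filter, limma on FPKM with other pseudocounts (1 and 0.1), filters, scalings and variance settings, a fold change of at least 2, a replicate block, leaving out each library, and other list tests. Library sizes without scaling factors and counts divided by 4 were added after seeing the data. In simulated data for the comparison of Alb-Cre Prdx1 fl/fl with Prdx1 fl/fl, with 18931 genes of which 100 were changed 2-fold and 100 were changed 4-fold, edgeR recovered 48% and 73% of them. False calls made up 5.47% of the calls of edgeR, 15.33% of those of DESeq2 and 10.31% of those of limma on FPKM. In the same simulation, camera called the 1 changed list and 0 of 20 unchanged lists. Genes were drawn independently there, so this does not show how often camera calls lists of correlated genes. Far fewer genes were changed than the 37.9% of tested genes called in the data, so the recovery may differ in the data. The chromosome copies of the major urinary protein (Mup) genes and the nuclear copies of mitochondrial genes are nearly identical, so their counts depend on how shared reads were assigned, which is not given in the sources used here.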

Results

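The livers of 3 Prdx1 fl/fl control mice and 3 Alb-Cre Prdx1 fl/fl mice were compared after 5 weeks on MCD. Cre recombinase under the albumin promoter removes floxed DNA in hepatocytes. The comparison asks how hepatic gene expression on this diet differs when Alb-Cre is present and peroxiredoxin 1, a peroxide-reducing enzyme, is lost. The controls carried no Cre, so an effect of the transgene itself cannot be separated from that of the loss. All mice were kept on MCD, so a difference that depends on the diet cannot be told from one present without it. Whether liver cells other than hepatocytes also lost Prdx1 was not tested. Deposited counts totalled 63189210, 67319086 and 66115966 in the controls and 58790874, 78291273 and 77300027 in the knockouts. Counts were found for 20977 ± 87.0 genes in the controls and 22898 ± 358 genes in the knockouts (SD, n = 3 each). The labels give no litter, batch or sequencing date. The p-values of single genes measure the spread among these mice. Those of camera with its preset correlation, of Fisher's exact test and of permutations over genes compare genes with other genes. They should not be read as a measure of the spread among mice.

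Prdx1 (ENSMUSG00000028691, chromosome 4, 116685544 to 116700822, plus strand, GRCm38) was lower in the knockouts, in the direction of the genotype labels. It stood at 626 ± 49.5 CPM in the controls and 88.3 ± 19.6 CPM in the knockouts (SD, n = 3 each), or 14.1% of the control mean. The 3 control libraries had 644, 570 and 663 CPM and the 3 knockout libraries 78.7, 111 and 75.4 CPM. The log2 fold change was -2.82 ± 0.17 (SE), with an adjusted p of 4.4e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. The labels do not say which exons are floxed, so reads from outside them may add to the remaining signal.

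**Figure D1:**
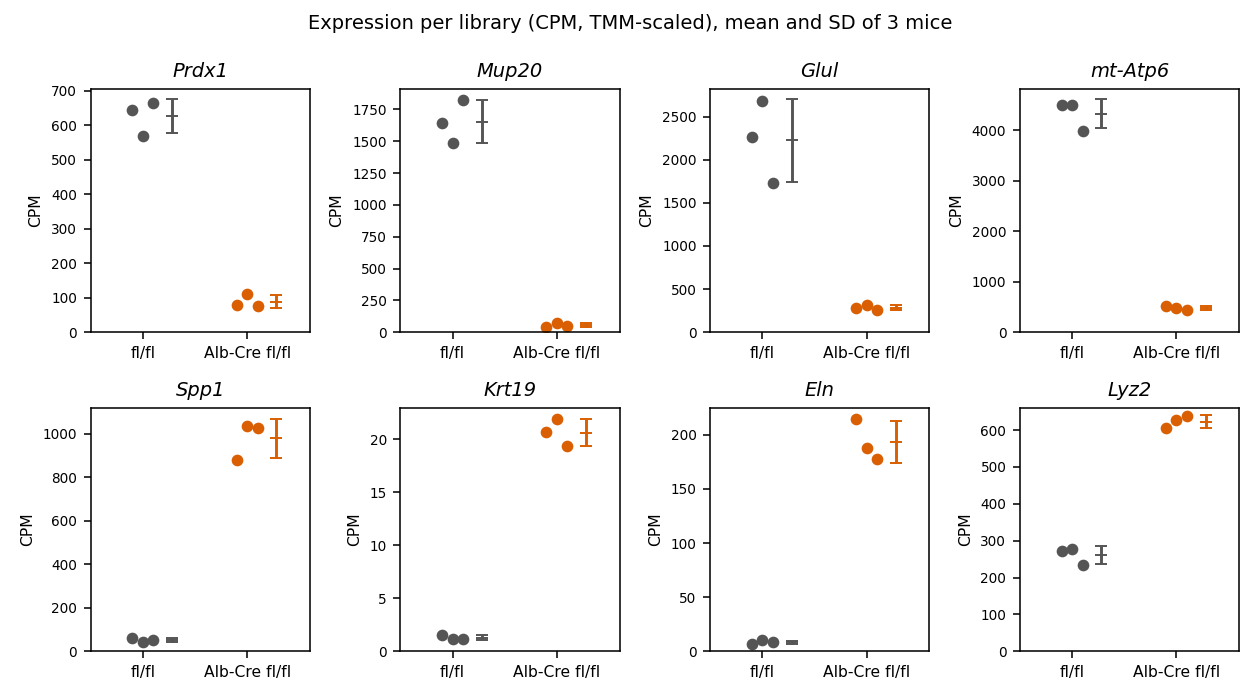
Expression per library in CPM, TMM-scaled and on linear axes from 0, for 8 genes. Dots are single mice and bars are the mean and SD of 3 mice. Prdx1, Mup20, Glul and mt-Atp6 were lower in every knockout library than in every control library, and Spp1, Krt19, Eln and Lyz2 were higher.

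Knockout livers had higher levels of extracellular matrix, bile duct and macrophage genes and lower levels of many hepatocyte genes. Elastin (Eln) was at 8.50 ± 1.44 CPM in the controls and 193 ± 19.1 CPM in the knockouts. Osteopontin (Spp1), which ductular cells express, was at 52.6 ± 8.22 and 980 ± 88.5 CPM. Mup20, a male-enriched urinary pheromone carrier made by hepatocytes, was at 1652 ± 169 and 54.3 ± 17.4 CPM (SD, n = 3 per group throughout). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3767 of 18931 genes were higher and 3415 lower in the knockouts, and 2329 and 725 of them differed at least 2-fold. The groups did not overlap for 5447 higher and 4590 lower genes, 53.02% of those tested, against 10% by chance. The first principal component held 60.2% of the variance and separated the genotypes.

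The balance of the calls depended on how the libraries were scaled. With library sizes alone, 6459 genes were higher and 1249 lower, and with limma on the deposited FPKM, 5385 and 1306. The median log2 fold change of all genes was 0.05 with TMM factors, 0.41 with library sizes alone and 0.26 in the FPKM. Fold changes below use TMM factors. Relative to the median of all genes, the list medians described as higher or lower by camera kept their sign under TMM, RLE, library sizes and FPKM. Subtracting that median removes any shift common to all genes, so this does not test the effect of scaling. Without the subtraction, the NRF2, interferon and acute phase medians were -0.25, -0.35 and -0.20 with TMM factors. With library sizes alone they were 0.12, 0.02 and 0.16.

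**Figure D2:**
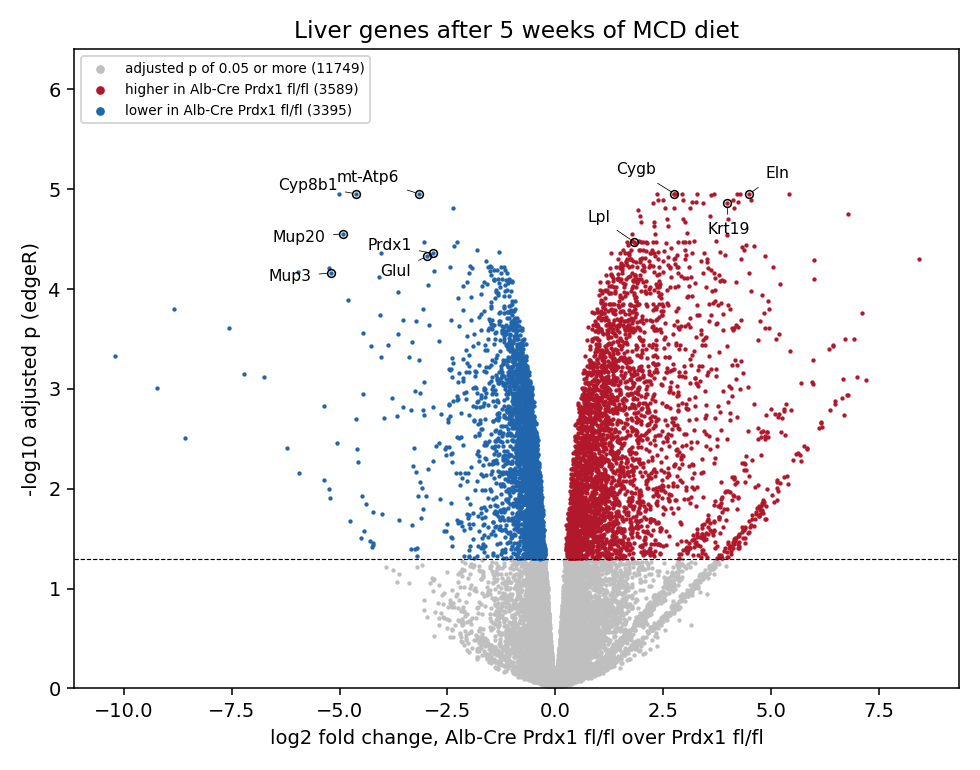
The log2 fold change of each tested gene (x axis) against the -log10 adjusted p of edgeR's quasi-likelihood test (y axis), with the dashed line at an adjusted p of 0.05. Red points are 3589 genes higher in the knockouts, blue points are 3395 lower, grey points are 11749 that did not pass, and 198 genes with a group at 0 in all libraries are left out. Named genes are circled.

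Ranked by the fitted log2 fold change, as the rule fixed before the data were examined asks, the highest genes had no counts in any control library. Only a lower bound on their fold can be given, and genes with a few control counts may rank among them by such bounds. Myo18b, a myosin (chromosome 5, 112688876 to 112896362), reached 9.96 ± 1.76 CPM, at least 144-fold above the floor of the control group. Clic6, Cyp3a41a, Arnt2 and Fam163a were at least 94.7-fold, 90.8-fold, 90.3-fold and 75.8-fold higher. Ppp2r2b, Gabrp, Clca3a2 and Itgb6, the last an integrin subunit of epithelia, were at least 72.0-fold, 62.8-fold, 56.0-fold and 54.2-fold higher. Wfdc15b, Ttc22 and Hs6st2 were at least 40.0-fold, 32.4-fold and 30.6-fold higher. In all, 178 genes past the threshold had no counts in the controls, and 20 had none in the knockouts.

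Ranked the same way, the lowest genes were mostly Mup genes, which lie in a cluster of near-identical copies on chromosome 4, so the value of a single copy is uncertain. Mup22 (60817589 to 60821463) fell from 597 ± 313 CPM to no counts, at least 12100-fold. Mup12, Mup14, Mup19 and Mup1 fell at least 977-fold, 740-fold, 233-fold and 107-fold, and Mup17, Mup13 and Mup8 at least 54.9-fold, 41.6-fold and 20.4-fold. Mup10, whose knockout mean lay below the floor, fell at least 341-fold, and Mup7 fell by 9.24 on the log2 scale. Slc45a2 and Slc15a5, both solute carriers, had no counts in the knockouts, at least 30.0-fold and 27.7-fold lower. For 7 of these 12 genes the fold moved by over 1.5 times when a control mouse was left out. Without control replicate 2 the bounds were 302-fold for Mup12, 152-fold for Mup19, 38.1-fold for Mup1 and 173-fold for Mup10, and the control mean of Mup7 was 302 times the knockout mean in place of 668 times. The bound of Mup14 was 476-fold without control replicate 3 and that of Mup8 was 7.80-fold without control replicate 1.

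Matrix genes rose as a group. Of 44 tested members of the extracellular matrix and fibrosis list, 39 rose, 3 fell and 2 did not pass (40 up and 3 down adjusted over the list alone). The median log2 fold change was 1.80, with a camera adjusted p = 3.6e-41 and an adjusted p = 0.0386 with an estimated correlation. Eln rose by 4.51 ± 0.16 (log2, SE), the collagen-binding proteoglycan Lum by 2.37 ± 0.09, the fibroblast receptor Pdgfra by 2.75 ± 0.10 and the protease inhibitor Timp3 by 2.26 ± 0.09. The members that fell, named after their values were seen, were Mmp13 at -2.14, Fn1 at -0.48 and Postn at -0.46. Stellate cell markers moved with them: 12 of 18 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.90. Cygb went from 22.8 ± 0.970 to 155 ± 9.63 CPM, Pdgfrb rose by 2.21 ± 0.13 and Dcn by 1.29 ± 0.09, and Colec10 fell by 2.25 ± 0.18. Hhip at -2.75, Ecm1 at -0.55 and Steap4 at -0.30 (0.07 with library sizes alone), which also fell, were named after their values were seen. Camera called the stellate list (adjusted p = 2.6e-05), but not in the second version of the test (adjusted p = 0.146 with an estimated correlation).

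Bile duct genes rose further. Of 21 cholangiocyte and ductular markers, 16 rose, 2 fell and 3 did not pass (17 up and 2 down adjusted over the list alone). The median was 3.67, or 2.34 in the FPKM, with a camera adjusted p = 1.6e-24 and an adjusted p = 0.0363 with an estimated correlation. The keratin Krt19 rose by 3.98 ± 0.17 (log2, SE). Tspan8 went from 1.94 ± 0.0803 to 37.7 ± 2.71 CPM and Cd24a from 4.82 ± 0.610 to 59.1 ± 5.58 CPM. The members that fell, named after their values were seen, were Krt8 at -0.66 and Krt18 at -0.52, keratins that hepatocytes also express.

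Macrophage genes rose as well. Of 25 monocyte-derived macrophage markers, 21 rose, 0 fell and 4 did not pass (21 up adjusted over the list alone). The median was 0.91, with a camera adjusted p = 4.1e-10 and an adjusted p = 0.0363 with an estimated correlation. Trem2, a lipid-sensing receptor, went from 14.9 ± 1.12 to 49.9 ± 3.56 CPM and lysozyme (Lyz2) from 261 ± 24.6 to 623 ± 16.9 CPM, while Csf1r rose by 1.33 ± 0.10 and Fcgr1 by 1.58 ± 0.13. Of 16 Kupffer cell markers, 10 rose, 1 fell and 5 did not pass, also when adjusted over the list alone, with a median of 0.87. The complement genes C1qb and C1qc rose by 1.47 and 1.46, Vsig4 went from 58.1 ± 9.97 to 218 ± 12.5 CPM, and Fcna, named after its value was seen, stood at -0.69. All 10 tested genes of MHC class II presentation rose, with a median of 1.07, among them Ctss by 1.46, H2-DMa by 1.07 and Cd86 by 1.07. Of 8 NADPH oxidase and phagocyte oxidant genes, 6 rose, 1 fell and 1 did not pass, with a median of 1.04. Ncf1 rose by 1.80 and Cybb by 1.09, and Nox4, an oxidase of non-phagocytic cells that was named after its value was seen, fell by 1.05. Both lists gave the same counts adjusted over the list alone. By camera, the adjusted p was 2.9e-05 for the Kupffer, 2.3e-06 for the MHC class II and 0.000747 for the NADPH oxidase list. These calls were lost in the second version of the test (adjusted p = 0.296, 0.146 and 0.146 with an estimated correlation).

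Lymphocyte and neutrophil genes were measured at low levels. Of 21 T and NK cell markers, 7 rose and 14 did not pass, also adjusted over the list alone, with a median of 1.08, or 0.76 in the FPKM. Cd8a went from 0.496 ± 0.178 to 2.29 ± 0.397 CPM and Il2rb from 4.86 ± 0.591 to 8.34 ± 0.625 CPM. Some other members that rose lost their call when a library was left out, with adjusted p up to 0.116 in edgeR. Camera gave an adjusted p = 0.0390 (adjusted p = 0.344 with an estimated correlation). The call was lost without control replicate 1 (0.0650), without knockout replicate 2 (0.0571) and without knockout replicate 3 (0.0612). Of 9 neutrophil markers, 3 rose and 6 did not pass, also adjusted over the list alone, with a median of 0.97 and a camera adjusted p = 0.180. Csf3r rose by 1.43 ± 0.14 and S100a8 by 1.13 ± 0.25, and Ngp was at least 2.15-fold higher against controls with no counts. The Ngp call was lost without control replicate 2 (adjusted p = 0.0504 in edgeR) and without each knockout (0.0610 to 0.0625). Of 14 B and plasma cell markers, 3 rose and 3 fell (4 and 3 adjusted over the list alone), with a camera adjusted p = 0.731. Igkc rose by 2.48, Cd22 by 1.31 and Jchain by 3.38, while Pax5 fell at least 16.3-fold to no counts, and Derl3, named after its value was seen, fell from 2.18 ± 1.07 to 0.585 ± 0.214 CPM. The median of this list was 0.20 and its mean -0.27 with Pax5 at its bound.

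Markers of sinusoidal endothelium went both ways. Of 19, 5 rose, 4 fell and 10 did not pass, also adjusted over the list alone. F8 fell by 1.05, Dnase1l3 by 0.75 and Oit3 by 0.77, and Stab1 rose by 0.71. The others, named after their values were seen, were Clec4g at -0.67, Mrc1 at 0.46, Cdh5 at 0.41, Eng at 0.57 and Plxnc1 at 0.38. The median was -0.16, or 0.21 with library sizes alone, and the camera adjusted p = 0.376. Of 8 erythroid and platelet genes, Alas2 fell by 2.00 and Pf4 rose by 1.37, also adjusted over the list alone, and the camera adjusted p = 0.326. The Pf4 call was lost without knockout replicate 3 (adjusted p = 0.0532 in edgeR). The median of this list was 0.05, its mean -0.12 and its camera direction down. Of 17 pancreatic acinar and adipose genes, 2 were tested. Cela2a fell by 1.69 and Cela1 stood at -0.23 (0.14 with library sizes alone), and the Cela2a call was lost without each library except control replicate 2, with adjusted p from 0.0635 to 0.102 in edgeR.

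Hepatocyte markers fell. Of 29, 22 fell, 0 rose and 7 did not pass (23 down adjusted over the list alone), with a median of -0.68 and a camera adjusted p = 2.2e-12 (adjusted p = 0.157 with an estimated correlation). Glul, the glutamine synthetase of pericentral hepatocytes, went from 2224 ± 478 to 284 ± 31.5 CPM. Tat fell by 1.34, Cyp2e1 by 1.28 and the asialoglycoprotein receptor Asgr1 by 0.78. Albumin took 6.68% ± 0.809 of the deposited counts in the controls and 4.91% ± 0.534 in the knockouts.

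**Figure D3:**
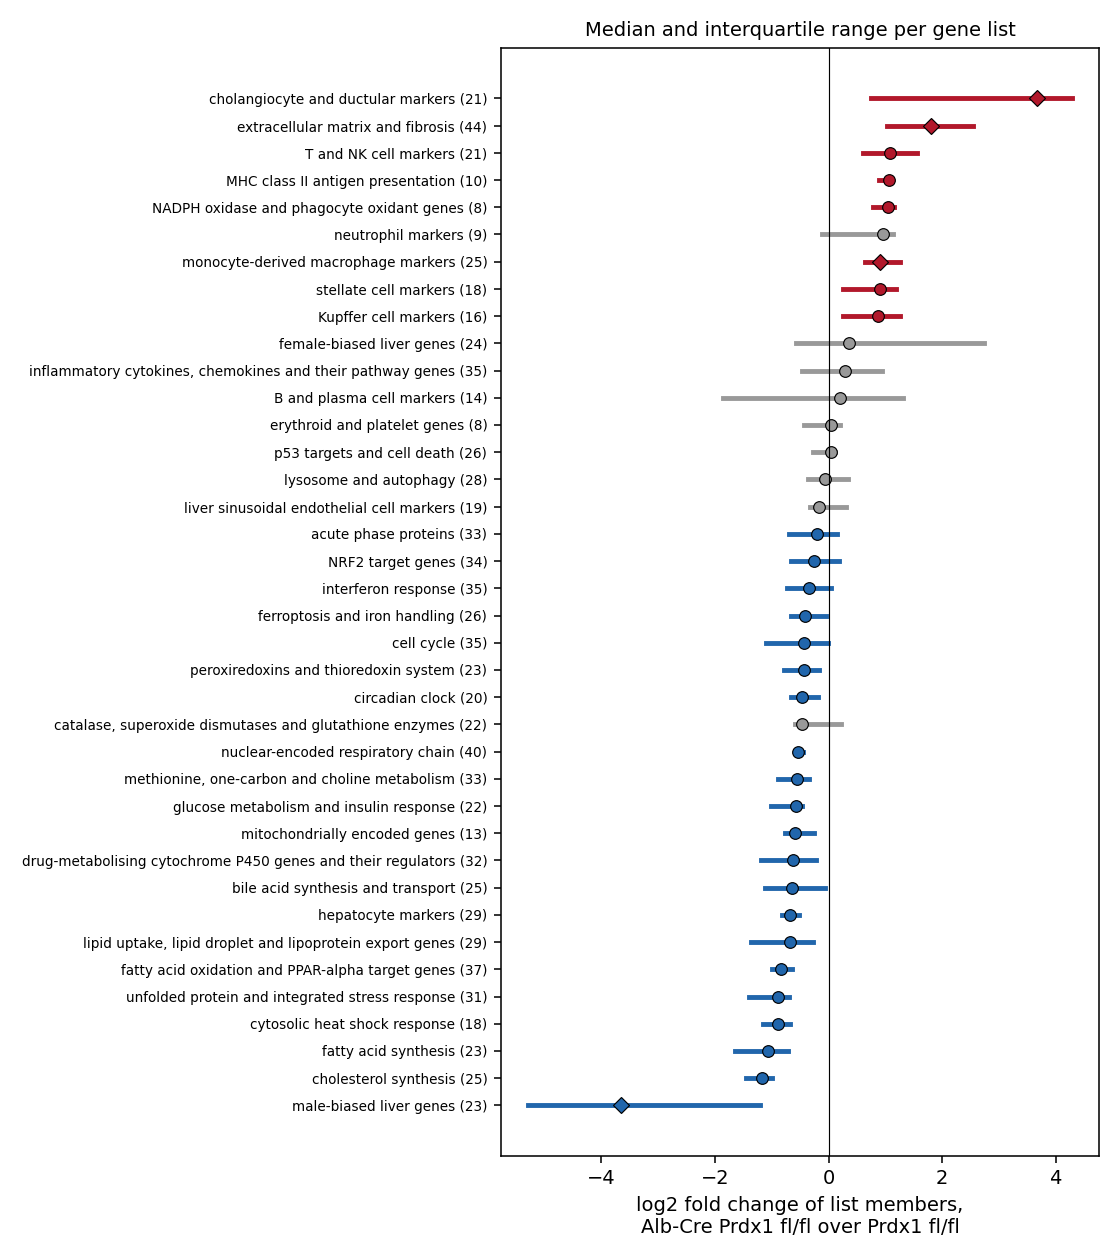
Median (marker) and interquartile range (bar) of the log2 fold changes of the tested members of 38 gene lists, with the number of members in brackets and genes with a group at 0 placed at their bound. Red and blue lists passed camera with the preset correlation, grey lists did not, and diamonds mark lists that also passed with an estimated correlation. Cholangiocyte and ductular markers had the highest median, 3.67, and male-biased liver genes the lowest, -3.65.

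Genes that male livers express more than female livers had the lowest median of the lists. Of 23 male-biased genes, 21 fell, 0 rose and 2 did not pass, also adjusted over the list alone. The median was -3.65, or -2.17 in the FPKM, with a camera adjusted p = 7.5e-17 and an adjusted p = 0.0363 with an estimated correlation. The 13 members on chromosomes other than that of the Mup cluster had a median of -1.33. Mup20 fell by 4.93 ± 0.25, Mup3 by 5.21 ± 0.35 and Mup21 by 3.65 ± 0.28, and the organic anion transporter Slco1a1 went from 91.5 ± 13.5 to 3.25 ± 1.54 CPM. Of 24 female-biased genes, 8 rose, 4 fell and 12 did not pass (8 and 5 adjusted over the list alone). Prom1, which ductular cells also express, rose by 4.42 and Cux2 by 4.12, while Slc22a27 fell by 1.87. Cyp17a1 at -2.31, Cyp4a14 at -1.29 and Cyp2b9 at -0.76, which also fell, were named after their values were seen. The camera adjusted p of this list was 0.0781, and 0.0282 without control replicate 1.

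Lipid genes fell in several lists, beside the fall of the hepatocyte markers (median -0.68). All 25 cholesterol synthesis genes fell, also adjusted over the list alone, with a median of -1.17. Hsd17b7 fell by 1.28, Fdft1 by 1.45 and Sc5d by 1.19. Of 23 fatty acid synthesis genes, 17 fell, 1 rose and 5 did not pass (19 down and 2 up adjusted over the list alone), with a median of -1.06. The desaturases Fads2 and Fads1 fell by 1.94 and 1.66, and Elovl3 by 4.07. Srebf1, named after its value was seen, rose by 0.50. Of 37 fatty acid oxidation and PPAR-alpha target genes, 27 fell and 10 did not pass (32 down adjusted over the list alone), with a median of -0.83. Vnn1 fell by 1.78 and Decr1 by 0.97, and the hormone Fgf21 went from 121 ± 33.9 to 23.1 ± 6.38 CPM. Of 29 genes of lipid uptake, droplets and lipoprotein export, 21 fell, 2 rose and 6 did not pass (21 down and 3 up adjusted over the list alone), with a median of -0.68. Fabp1 went from 1214 ± 190 to 277 ± 46.4 CPM, while lipoprotein lipase (Lpl) rose from 129 ± 8.39 to 456 ± 34.3 CPM. Fabp5, the other member that rose, at 0.91, was named after its value was seen. In camera these lists had adjusted p of 4.2e-13, 2.7e-09, 1.1e-11 and 4.9e-09 in order. None held in the second version (adjusted p = 0.139, 0.115, 0.245 and 0.115 with an estimated correlation).

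Other hepatocyte pathways fell beside the same markers. Of 25 bile acid genes, 15 fell, 3 rose and 7 did not pass, also adjusted over the list alone, with a median of -0.65. Cyp8b1, the sterol 12-alpha-hydroxylase, went from 215 ± 7.47 to 8.70 ± 1.82 CPM, and Baat fell by 1.49. The members that rose, named after their values were seen, were Slc51b at 1.73, Abcg5 at 0.74 and Abcc3 at 0.52. Of 32 drug-metabolising cytochrome P450 genes and regulators, 17 fell, 3 rose and 12 did not pass (17 and 4 adjusted over the list alone), with a median of -0.62. Cyp2f2 fell by 2.81 and Cyp2j5 by 1.61, while Cyp3a41a rose from no counts. Cyp3a13 at 0.53 and Cyp2c40 at 0.45, the others that rose, were named after their values were seen. Of 22 glucose genes, 14 fell and 8 did not pass, also adjusted over the list alone, with a median of -0.57, and Tat fell by 1.34 and Pck1 by 0.97. Of 33 methionine, one-carbon and choline genes, 22 fell, 2 rose and 9 did not pass (23 and 2 adjusted over the list alone), with a median of -0.56. Bhmt, the betaine-homocysteine methyltransferase, fell by 2.44, Dmgdh by 1.47, Pcyt2 by 1.04 and Sardh by 0.88. Phgdh, which rose by 1.68, was named after its value was seen. For these lists camera gave adjusted p of 2.9e-07, 6.3e-06, 6.8e-07 and 1.6e-06 in order. None held in the second version (adjusted p = 0.122, 0.138, 0.117 and 0.115 with an estimated correlation).

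Genes of the respiratory chain fell as well, beside the hepatocyte markers (median -0.68). Of 40 nuclear-encoded genes, 34 fell and 6 did not pass (36 down adjusted over the list alone), with a median of -0.53. Cycs fell by 1.10, Uqcrc2 by 0.94 and Uqcrfs1 by 0.83. Of 13 mitochondrially encoded mRNAs, 8 fell and 5 did not pass, also adjusted over the list alone. Their median was -0.59, or -0.22 with library sizes alone and -0.25 in the FPKM. The gene mt-Atp6, an ATP synthase subunit (mitochondrial positions 7927 to 8607), stood apart, going from 4326 ± 289 to 483 ± 41.2 CPM, a log2 fold change of -3.16 ± 0.11. Next in order, mt-Cytb fell by 0.99 and mt-Nd4 by 0.70. Both lists passed camera with adjusted p of 6.4e-11 and 2.0e-07 (adjusted p = 0.115 and 0.174 with an estimated correlation).

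Stress response genes fell beside the hepatocyte markers (median -0.68). Of 31 unfolded protein and integrated stress response genes, 25 fell and 6 did not pass (26 down adjusted over the list alone), with a median of -0.88. Hyou1 fell by 1.55, Dnajb9 by 1.42, Herpud1 by 1.14 and Creld2 by 1.58, all of the endoplasmic reticulum. Of 18 cytosolic heat shock genes, 17 fell and 1 rose, also adjusted over the list alone, with a median of -0.90. Dnaja1 fell by 1.17, Dnajb1 by 1.06 and Bag3 by 1.11, and the small heat shock protein Cryab, named after its value was seen, rose by 1.61. The camera test gave adjusted p of 1.9e-11 and 1.9e-09 (adjusted p = 0.245 and 0.138 with an estimated correlation).

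Antioxidant genes fell in part, beside the same markers. Of 23 other peroxiredoxin and thioredoxin genes, 13 fell, 2 rose and 8 did not pass (14 and 2 adjusted over the list alone). The median was -0.44, or -0.06 with library sizes alone and -0.09 in the FPKM. The mitochondrial Prdx3 went from 233 ± 2.82 to 117 ± 1.77 CPM, and Msrb1, Txn2 and Glrx5 fell by 0.98, 0.83 and 0.92. Sesn1 at 1.10 and Txnip at 1.17, which rose, were named after their values were seen. Camera adjusted p was 0.000189 (adjusted p = 0.115 with an estimated correlation). Of 34 NRF2 targets, 12 fell, 2 rose and 20 did not pass (13 and 3 adjusted over the list alone). Gstm2 fell by 1.03 and Me1 by 1.62, and G6pdx rose by 0.81. The other member that rose, Abcc3 at 0.52, was named after its value was seen. The NRF2 median was -0.25, or 0.12 with library sizes alone and 0.10 in the FPKM, and camera adjusted p was 0.0186 (adjusted p = 0.420 with an estimated correlation). This call was lost without control replicate 3 (adjusted p = 0.127). Of 22 catalase, superoxide dismutase and glutathione enzymes, 12 fell, 4 rose and 6 did not pass (13 and 4 adjusted over the list alone), with a camera adjusted p = 0.0749, or 0.0457 and 0.0280 without control replicates 1 and 2. Gstz1 fell by 0.72 and Sod2 by 0.70, while Sod3 rose by 0.70 and Gpx3, a secreted peroxidase, by 2.72. Ggt1, at least 35.4-fold higher against a control mean below the floor, and Gpx8 at 1.55, which also rose, were named after their values were seen. The median of this list was -0.47 and its mean 0.25. Of 26 ferroptosis and iron genes, 12 fell, 1 rose and 13 did not pass (13 and 2 adjusted over the list alone). The median was -0.42, or -0.05 with library sizes alone and -0.08 in the FPKM. Slc11a2 fell by 0.97 and the ferritin gene Ftl1 by 0.69, and Alox5, named after its value was seen, rose by 3.97. Camera adjusted p was 0.00712 (adjusted p = 0.117 with an estimated correlation).

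Inflammatory genes went both ways. Of 35 inflammatory cytokine, chemokine and pathway genes, 12 rose, 5 fell and 18 did not pass, also adjusted over the list alone, with a median of 0.28. The camera adjusted p was 0.0781, and 0.0492 without control replicate 2. Cx3cl1 rose from 2.51 ± 0.282 to 30.0 ± 4.13 CPM, and Cxcl14 and Tnfaip2 rose by 1.53 and 1.24. The members that fell, named after their values were seen, were Cxcl9 at -1.81, Cxcl10 at -1.80, Ccl7 at -2.02, Cxcl13 at -2.11 and Ccl2 at -0.51. Of 35 interferon response genes, 14 fell, 4 rose and 17 did not pass (17 and 4 adjusted over the list alone). Iigp1 fell by 1.03, Isg15 by 1.44 and Usp18 by 1.18. Oas2 at 0.80, Oasl2 at 0.84, Ifit2 at 0.57 and Irf1 at 0.38, which rose, were named after their values were seen. The median was -0.35, or 0.02 with library sizes alone and 0.01 in the FPKM. Of 33 acute phase genes, 11 fell, 2 rose and 20 did not pass (12 and 2 adjusted over the list alone). Mt2 fell by 1.55 and Saa4 by 1.19, and Osmr at 1.28 and Lcn2 at 0.73, which rose, were named after their values were seen. The median was -0.20, or 0.16 with library sizes alone and 0.14 in the FPKM. The adjusted p of camera was 0.0119 and 0.00821 for the interferon and acute phase lists (adjusted p = 0.497 and 0.469 with an estimated correlation).

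Of 35 cell cycle genes, 14 fell, 1 rose and 20 did not pass, also adjusted over the list alone. The median was -0.43, or -0.06 with library sizes alone and -0.07 in the FPKM. Rrm2 went from 15.8 ± 0.679 to 4.18 ± 1.09 CPM and Cdc20 from 12.4 ± 4.96 to 2.24 ± 0.788 CPM, and Hmgb2, named after its value was seen, rose by 0.63. Of 20 circadian clock genes, 7 fell and 13 did not pass, also adjusted over the list alone, with a median of -0.46, or -0.05 in the FPKM, and Hlf fell by 0.84 and Ciart by 2.18. Camera adjusted p was 0.00227 and 0.0167 (adjusted p = 0.344 and 0.245 with an estimated correlation). Of 26 p53 target and cell death genes, 3 rose, 4 fell and 19 did not pass, also adjusted over the list alone. Phlda3 rose by 1.85 and Sesn1 by 1.10, Gdf15 fell by 1.37 and Aen by 0.75, and the others, named after their values were seen, were Zmat3 at 0.55, Trp53inp1 at -0.87 and Fas at -0.54. The camera adjusted p was 0.662, with a median of 0.04 and a camera direction of down. Of 28 lysosome and autophagy genes, 8 rose, 7 fell and 13 did not pass (8 and 8 adjusted over the list alone), with a camera adjusted p = 0.869. Ctsk rose by 2.40 and Lgmn by 1.23, and the autophagy receptor Sqstm1 fell by 0.84. The median of this list was -0.07 and its mean 0.08.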

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

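Over 173 genes named by the rule and 3659 comparisons, 75 lost the call, 13 gained it and 3571 stayed on the same side of the threshold. Direction turned in 9 comparisons, all of Cela1, which did not pass in any of them. Among all list members that passed with TMM factors, 18 turned under some alternative, Steap4 among them, and 0 of these passed in the other direction. The number of lower genes depended on scaling: against 3415 with TMM factors, limma gave 1306 on log2(FPKM + 0.5), 1308 with a pseudocount of 1, 1295 with 0.1, 1256 with a mean FPKM of at least 1 and 1149 with no filter (5978 higher). It gave 1215 without a variance trend, 1298 with robust variances and 1360 with array weights. Library sizes alone, chosen after seeing the data, gave 6459 higher and 1249 lower. These settings leave the knockouts shifted upward (median of all genes 0.26 in FPKM and 0.41 with library sizes), and limma on FPKM after median ratio scaling gave 2980 higher and 3440 lower. Of the 7182 genes called by edgeR, 4222 were called on log2(FPKM + 0.5) and 6012 after median ratio scaling. A fold change of at least 2 left 2329 higher and 725 lower by construction. Counts divided by 4, also chosen after seeing the data, gave 3880 and 3494.

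Of 8 lists higher and 21 lower with camera's preset correlation, 3 and 1 held with an estimated correlation, and fry, which does not compare a list with other genes, called 13 and 19. Quantile normalization of FPKM left 10 lower lists, and the direction of 3 lists turned without passing the threshold: mitochondrially encoded genes (adjusted p = 0.731), acute phase proteins (0.188) and NRF2 targets (0.448). The cause was not tested.

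Leaving out each library gave 2892 to 3645 higher and 2641 to 3104 lower genes, 7 to 9 lists higher and 20 to 22 lower, and a Prdx1 log2 fold change of -3.02 to -2.71. The replicate numbers did not pair the mice: deviations of same-numbered libraries correlated at 0.016, 0.031 and 0.035, although each library correlated best with its own number in the other genotype. With a replicate block, 3232 genes were higher and 3155 lower, 7 lists higher and 22 lower, and Prdx1 was at -2.84. With 3 mice per genotype and far fewer changed genes than were called in the data, edgeR recovered 48% of the simulated 2-fold changes. Genes that did not pass are therefore not shown to be unchanged.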

Other observations

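All tests and lists in this part were chosen after the results were seen. Beside the bile duct markers, 12 of 16 Notch pathway genes rose and 0 fell, with a median log2 fold change of 0.73. Jag1, a ligand that specifies bile ducts, rose by 2.02 ± 0.18 (SE), and Sox4 went from 4.37 ± 0.185 to 38.3 ± 4.92 CPM (SD, n = 3). Of 18 YAP and TEAD target genes, 11 rose and 1 fell (median 0.54). Of 14 smooth muscle and portal fibroblast genes, 10 rose and 0 fell (median 1.28), among them Cd34 by 3.22. Smooth muscle members were mixed. Tagln rose by 1.11 and Acta2 by 1.04, while Lmod1 at 1.35, Myh11 at -0.28 and Cnn1 at -1.42 did not pass, nor did Gli1 at 2.03. Of 12 oncofetal genes, 4 rose and 1 fell, including H19 by 2.64, and of 7 mesothelial genes, 2 rose and 2 fell. Camera adjusted p was 1.2e-05, 1.1e-06, 1.5e-06, 0.151 and 0.753 in this order (adjusted p = 0.0510, 0.0393, 0.0393, 0.217 and 0.837 with an estimated correlation). In the deposited KEGG annotation, tested by Fisher's exact test over 5974 annotated genes and 608 comparisons, 72 terms were enriched among higher genes and 45 among lower genes. Lower genes held 95 of 154 genes of protein processing in the endoplasmic reticulum, against 40.2 expected by chance, 27 of 30 of the citrate cycle and 33 of 44 of the proteasome. Higher genes held 46 of 69 genes of ECM-receptor interaction and 88 of 179 of focal adhesion.

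A hypothesis was tested that pericentral genes were lower than periportal genes. The pericentral median was -1.24 (15 of 21 fell) and the periportal median -0.58 (8 fell and 2 rose), a difference of -0.66 with a permutation p of 0.0101 over genes, which are not independent. The difference of medians would go with a larger loss of pericentral expression, but it was found and tested on the same mice. Members varied within both lists. The periportal genes that rose were Cdh1 at 1.68 and Ctsc at 0.49, and the periportal Cyp2f2 fell by 2.81. The pericentral genes that did not pass were Lgr5 and Cyp2c54 at -1.13, Nr1i3 at -0.57, Tbx3 at -0.49, Axin2 at -0.18 and Slc1a4 at 0.09.

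Male-biased genes fell by more than the hepatocyte markers. A lower share of hepatocyte RNA would lower both alike, but the male-biased median lay below that of the hepatocyte markers. The difference was -2.97 (permutation p = 1e-05 over genes, the smallest 100000 resamples can give). Near-identical Mup copies are not independent, so this p overstates the evidence. For members on other chromosomes the median was -1.33, against -0.68 for the hepatocyte markers. Reads moved between Mup copies would leave their sum in place, but the control mean of the summed CPM of 49 Mup genes and pseudogenes was 45.1 times the knockout mean. Chromosome 4 holds both Prdx1 and the Mup cluster. Both groups carried the same floxed Prdx1 alleles, so linkage to these alleles predicts no difference between the groups. The labels do not say whether the mice differed elsewhere on this chromosome. A chromosome 4 variant that acts only on genes near it would leave members on other chromosomes in place. However, 11 of 13 of those fell, with a median of -1.33 (permutation p = 0.00224 over genes, against the hepatocyte markers). This cannot address a chromosome 4 variant that acts on genes of other chromosomes. A variant within the Mup cluster itself stays open for the fall of the Mup genes only. A chromosome 4 variant that acts on other chromosomes and an effect of the genotype on sex-dependent transcription also stay open.

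The fall of mt-Atp6 was larger than that of its neighbours. Its log2 fold change lay at -2.17 relative to the lowest of the other 12 mitochondrial mRNAs. Those 12 had a median of -0.53 with TMM factors. The median of the whole list was -0.59 with TMM factors, -0.22 with library sizes alone and -0.25 in the FPKM, so the size of a common fall depends on scaling. Still, mt-Atp6 fell by more than a common fall would give. The nuclear copy Gm10925 on chromosome 1 did not gain what mt-Atp6 lost. Gm10925 went from 4365 to 2218 CPM, a change of -2147 CPM (knockout mean minus control mean). It is among 7 copies there that were all lower in every knockout library (log2 fold changes from -1.01 to -0.33). A net fall does not exclude that part of the mt-Atp6 reads moved there, because the assignment of shared reads is not given. The sum of mt-Atp6, the overlapping mt-Atp8 and the adjacent mt-Co3 lay at -0.48 relative to the median of the other 10 on the log2 scale, but at -1.01 it was close to the lowest of them (-0.99), so reads moved to mt-Atp8 or mt-Co3 stay open. A difference in mitochondrial sequence between the mice may also explain it and needs the reads, which were not analysed here.

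Ductular markers rose by more than markers of other cells. A lower share of hepatocyte RNA would raise markers of all other cell types alike. The ductular median exceeded that of sinusoidal endothelium, -0.16, by 3.83 (permutation p = 6e-05 over genes). Medians of the Kupffer, stellate, macrophage, neutrophil and T and NK lists were higher, from 0.87 to 1.08, and that of B and plasma cells was 0.20. The gaps to these lists were smaller and were not tested. Scaling factors shift all lists alike, so they bear on the ductular median itself and not on the gaps between lists. That median was 3.66 with RLE factors, 4.04 with library sizes alone and 2.34 in the FPKM. The FPKM values also differ by a pseudocount and another gene filter. More ductular cells, or ductular genes switched on in hepatocytes, may both give this pattern, and bulk RNA cannot separate them.

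The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes, with 7182 against at most 0 in the others by edgeR. For the lists, 1 split also gave as many, with 29 against at most 24. Each group in the other splits holds 2 libraries of a genotype and 1 of the other, which keeps part of the genotype difference. The rest of that difference adds to the spread within groups, which works against calls of single genes. These counts therefore do not show how many genes edgeR, or how many lists camera, would call by chance.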
